A study of Homo sapiens with 20 samples.

How the data were processed

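The series tests Mirror bisulfite sequencing (Mirror-seq), a method that reads 5-hydroxymethylcytosine (5hmC) at single bases, on human genomic DNA. In Mirror-seq a new strand is synthesised opposite each parental strand, and a CpG of the new strand is methylated by an enzyme only where the parental CpG carries no glucosylated 5hmC. After bisulfite treatment, which converts unmethylated cytosine, an unmethylated read at a CpG of the new strand therefore marks 5hmC on the parental strand. TAB-RRBS is a different chemistry, in which 5hmC is protected and all other methylated cytosine is oxidised, so that 5hmC alone is read as cytosine. These are background statements about the chemistries. The labels describe the libraries as derived from reduced representation bisulfite sequencing, which samples CpG-rich fragments, and do not say which step was left out of the negative controls.

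The 20 libraries were grouped by their titles into 18 groups. The group of the brain libraries titled 400 held 2 libraries, A and B, and so did the group of their negative controls. Every other group held 1 library. The number 400 in these titles carries no unit in the labels, whereas the titles of 2 further brain libraries give inputs of 200 ng and 100 ng. Nothing in the labels says whether A and B came from separate donors or separate DNA extractions, so differences between them may be technical only. The titles and the names of the deposited files give opposite assignments for the 2 TAB-RRBS libraries. The titles were used, these libraries are called "the library labelled" throughout, and the exchanged assignment was an alternative. The naming of the deposited files also sorts the libraries into sets: the 400 libraries with their controls, the 2 libraries with stated input, the 4 tissues and the cell line with their controls, the tumor pair, and the TAB-RRBS pair. Whether these sets are sequencing batches is not stated. Each library and its own control lay within the same set. Differences between the 400 libraries and the Brain, 200 ng and 100 ng libraries lie between sets and cannot be separated from them.

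Each deposited file held a row per CpG cytosine, with the cytosines of both strands listed apart. Each row gave a pair of whole read numbers, k of n, and a score that the authors deposited as k/n in thousandths. No file header or label says which reads k counts. Here k was taken as the reads counted as 5hmC, because its share was low in all 7 Mirror-seq negative controls. This reading was inferred from the values. All 112672764 rows parsed, k never exceeded n, and the score differed from k/n by at most 1 thousandth in every row. The genome build was hg19, per the submitters' processing notes. The aligner, the caller and their settings are not given in the sources used here, nor is whether duplicate reads were removed.

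Only the 22 autosomes were analysed. The 4071864 rows on the sex chromosomes, the mitochondrial genome and other contigs were left out of the comparisons. The level of a cytosine is the percentage k/n, and the mean level of a library is the mean over cytosines with at least 10 reads in every library of the comparison. Reads summed over autosomal CpG cytosines, a read counting at each cytosine it covers, ran from 45.2 M in the Liver control to 127 M in 400B. Reads summed per window count in the same way. Counting error was small beside the differences between libraries: the pooled share of the Liver library, 5.85%, had a 95% Wilson interval of 5.84 to 5.86%. Such intervals cover counting error only. They take counts as independent, but a read counts at each cytosine it covers, and reads from amplified DNA are not independent molecules.

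The comparison across library pairs used an exact two-sided sign-flip permutation test on the 7 differences between a Mirror-seq library and its own control; the smallest p it allows is 0.0156. The 400 libraries were compared with their controls by region with limma on the log2 odds of the reads summed per window, with 0.5 added to each count, Benjamini-Hochberg adjusted p below 0.05, 4 libraries and no block. Windows were 100 kb of hg19 with at least 20 cytosines. Individual cytosines were compared between the 2 libraries of each pair with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment at 0.05. With 1 library on each side, such a call compares 2 libraries and not 2 conditions. The same test between 400A and 400B and between their controls served as a yardstick. Tissue and tumor windows were compared with the 99th percentile of the difference between 400A and 400B over windows. Context was the number of covered CpGs within 100 bp on each side. Correlations across cytosines or windows are descriptive, because these are not independent replicates.

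The windows named in the text follow a rule that, like the tests and the alternatives listed last, was fixed before the data were examined. For the 400 libraries they are the 15 with the largest difference among those higher, and the 5 with the largest fall among those lower. For each of the 4 tissues they are up to 8 with the largest positive difference from the mean of the other tissues past the limit. For the tumor pair they are up to 10 falls and 10 rises past the limit. No single cytosine is named. No hg19 gene annotation was used here, so the comparisons planned by gene used windows, as fixed beforehand for that case. The 12 gene lists were not tested here, promoter and gene body context was not computed, and no gene is named for a window.

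The Fisher calls were tested on simulated reads at 500000 cytosines with the depths of 3 pairs. At the depths of the 400A pair 64.6% of simulated 40-point differences were called, 19.6% of 20-point and 2.73% of 10-point differences, and 7 of 440000 unchanged cytosines were called. At the depths of the Brain pair the 40-point share was 24.9%, and at those of the DKO pair 40.9%. These reads were drawn binomially around a background level shared by all cytosines of a pair. Real controls varied more: the difference between the 400A and 400B controls had an SD 1.53 times that of binomial sampling. Between these controls 1178 of 2778330 cytosines were called higher and 1549 lower, so the simulated share of false calls need not hold for real reads. The adjusted threshold also depends on how many cytosines differ, so the simulated shares called need not hold either. The limma step was tested on 15822 simulated windows of which 200 were changed. It called 32% of the windows with 2-fold higher odds, 86% at 3-fold, 100% at 5-fold and none of 50 at 1.5-fold. Of 15622 unchanged windows it called 1 higher and 4 lower. With real reads limma called 14750 of 15822 windows higher, so the adjusted cut-off differed and the simulated shares need not hold there.

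The alternatives fixed in this way were coverage minimums of 5 and 20 reads, pooled reads, cytosines covered in every Mirror-seq library, leaving out the top percentile of coverage, reads thinned to 10, a threshold of 0.01, a minimum difference of 10 points, both cytosines of a CpG summed, the replicate letter as a block, leaving out a replicate or a pair, other window minimums and added counts, no control subtraction, the 95th percentile as limit, exchanged TAB-RRBS labels and density within 500 bp. Others were added later and are named where they are used. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, R 4.3.3 and limma 3.58.1.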

Results

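5hmC was profiled at CpG cytosines of human DNA with Mirror-seq in brain, liver, kidney and spleen, in a cell line labelled DKO, and in a liver tumor with adjacent normal liver. Of the 18 Mirror-seq libraries, 7 were negative controls, each belonging to 1 library: 400A, 400B, Brain, Liver, Kidney, Spleen or DKO. The brain libraries 400A and 400B were the only replicates. The 200 ng and 100 ng brain libraries and the tumor and adjacent normal liver libraries had no control of their own. A brain TAB-RRBS library and its negative control provided a comparison with another chemistry. Between 1641983 cytosines in the 100 ng library and 3491668 in the library labelled TAB-RRBS control had at least 10 reads, and the median depth of all listed cytosines ran from 5 reads in the Liver library to 12 in the 400A control. Apart from the 400 libraries and their controls there were no replicates, and values of single libraries carry no replicate error.

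Brain DNA gave the highest Mirror-seq levels, liver, spleen and kidney intermediate levels, and the DKO cell line a level close to its control. The mean level over cytosines was 10.1% in 400A against 3.15% in its control, 9.23% in 400B against 3.22%, and 8.81% in the Brain library against 3.14%. The 400 pair difference was 6.48 ± 0.66 percentage points (SD, n = 2). Liver exceeded its control by 1.92 points, 4.69% against 2.77%. Spleen exceeded its control by 1.39 points, 4.92% against 3.53%. Kidney exceeded its control by 1.18 points, 4.35% against 3.17%. The DKO library, at 3.02%, exceeded its control by only 0.0701 points. Each of these 7 libraries was above its control on 22 of 22 autosomes. The 7 controls averaged 3.13% ± 0.23 (SD, n = 7), so the DKO difference was smaller than the spread between controls. Over the 7 pairs the mean difference was 3.31 points, higher in 7 of 7 pairs, with p = 0.0156 in the exact two-sided sign-flip test, the smallest value this design allows. The test takes the 3 brain pairs as independent, which the labels do not state. With these averaged to 1 pair, chosen after seeing the data, the mean was 2.15 points, higher in 5 of 5 pairs, and the exact test gave p = 0.0625, the smallest that 5 pairs allow.

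**Figure D1:**
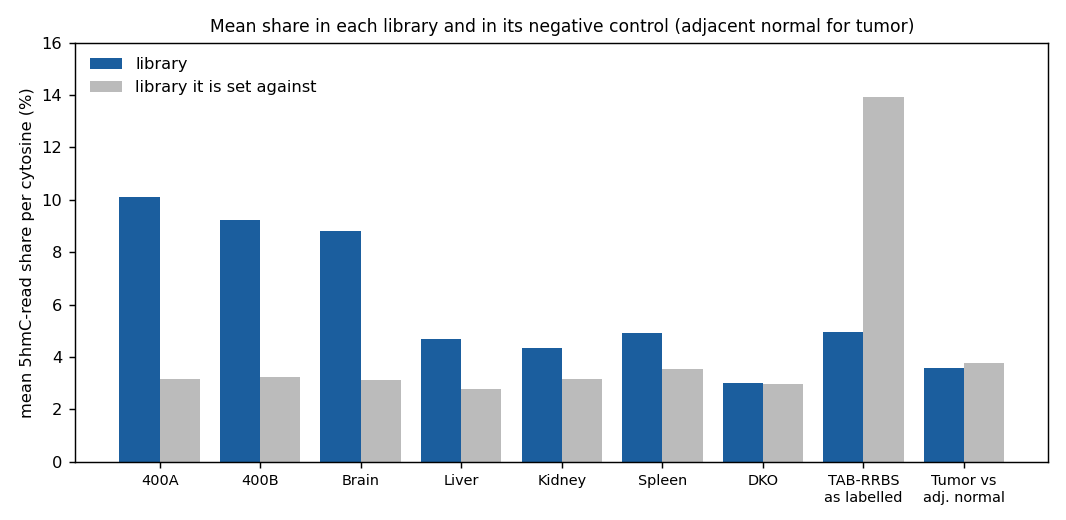
Mean percentage of reads counted as 5hmC per cytosine (vertical axis) in each library (blue) and in the library it was set against (grey: its negative control, or adjacent normal liver for the tumor), over cytosines with at least 10 reads in both. The 3 brain libraries stand at 8.81 to 10.1% over controls near 3%, DKO and its control are nearly level, and in the TAB-RRBS pair the library labelled control is the higher.

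Within brain, nearly the whole covered genome lay above control in the 400 libraries. Of 15822 windows of 100 kb, 14750 (93.2%) were higher than control and 5 were lower by limma at an adjusted p below 0.05. With so many windows called higher, this threshold bounds false calls over all called windows and not among the 5 lower ones. By limma 6 windows were lower at an unadjusted p below 0.05. Both the A pair and the B pair were above their control in 15493 windows. The median window difference was 5.4 points, and the middle of the range was wide, from 1.08 points at the 5th percentile to 14.0 points at the 95th. The region with the largest difference was chromosome 14, 39400001 to 39500000 (hg19), where 31 cytosines gave 34.7% in 400A and 30.5% in 400B against 3.10% and 1.84% in the controls, a rise of 4.28 ± 0.29 (SE) on the log2 odds scale (limma adjusted p = 8.0e-05, 1361 to 1579 reads per library). It was followed by chromosome 20, 11200001 to 11300000, with 38.8% and 28.6% against 3.9% and 4.01%. On chromosome 2, the window 85200001 to 85300000 gave 27.8% and 31.9% against 2.20% and 1.62%, and on chromosome 1, 39600001 to 39700000 gave 32.3% and 28.8% against 3.25% and 2.61%.

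The other 11 of the 15 windows with the largest rise differed by 24.6 to 27.2 points. They were chromosome 4 at 41000001 to 41100000, chromosome 3 at 12600001 to 12700000, chromosome 2 at 72900001 to 73000000, 54800001 to 54900000 and 44400001 to 44500000, chromosome 7 at 37000001 to 37100000, chromosome 9 at 97600001 to 97700000 and 8700001 to 8800000, chromosome 12 at 12600001 to 12700000, chromosome 10 at 65100001 to 65200000 and chromosome 11 at 36000001 to 36100000. In the Brain pair, which did not enter the choice, 12 of the 15 windows were measured with at least 10 cytosines. As means over cytosines, all 12 were above the Brain control, with a median difference of 21.9 points and a range of 11.3 to 44.3 points. The same windows exceeded control by a median of 5.52 points in Spleen (15 of 15 above), 4.41 points in Liver (14 of 14) and 4.39 points in Kidney (14 of 14). In DKO the median was 0.178 points, with 10 of 15 above. Most windows lay above control in any case: of 9322 measured in all 4 tissues, 93.8% in Brain, 86.6% in Liver, 76.2% in Spleen and 74.2% in Kidney. Among the windows of each pair, the named ones had a median percentile of 99.6 in Brain, 97.6 in Spleen, 95.7 in Kidney, 91.9 in Liver and 57.4 in DKO.

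Of the 5 windows below control, 2 had high levels in every library. Chromosome 10, 42300001 to 42400000, gave 40.3% and 40.5% in 400A and 400B against 48.4% and 48.1% in the controls, and chromosome 2, 133000001 to 133100000, gave 16.5% and 15.2% against 21.8% and 21.9%. The remaining 3, on chromosome 5 at 147700001 to 147800000, chromosome 18 at 32000001 to 32100000 and chromosome 1 at 78900001 to 79000000, fell by 1.43, 1.21 and 1.05 points. None of the 5 kept an adjusted p below 0.05 when the library 400A was left out of the limma fit, whereas all 15 windows above control did. The log2 odds differences of the windows on chromosomes 10 and 2 were then -0.45 and -0.65, against -0.46 and -0.57 with 4 libraries. Those on chromosomes 5, 18 and 1 went from -0.96, -0.73 and -0.75 to -0.38, -0.38 and -0.60. Without 400B these last 3 windows kept their call. Without 400A limma called 2 windows lower, and without the 400A control 11. As means over all cytosines covered in each pair, which changes both the measure and the cytosines, 2 of the 5 windows lay above control in the A pair and 3 of the 5 in the B pair.

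**Figure D2:**
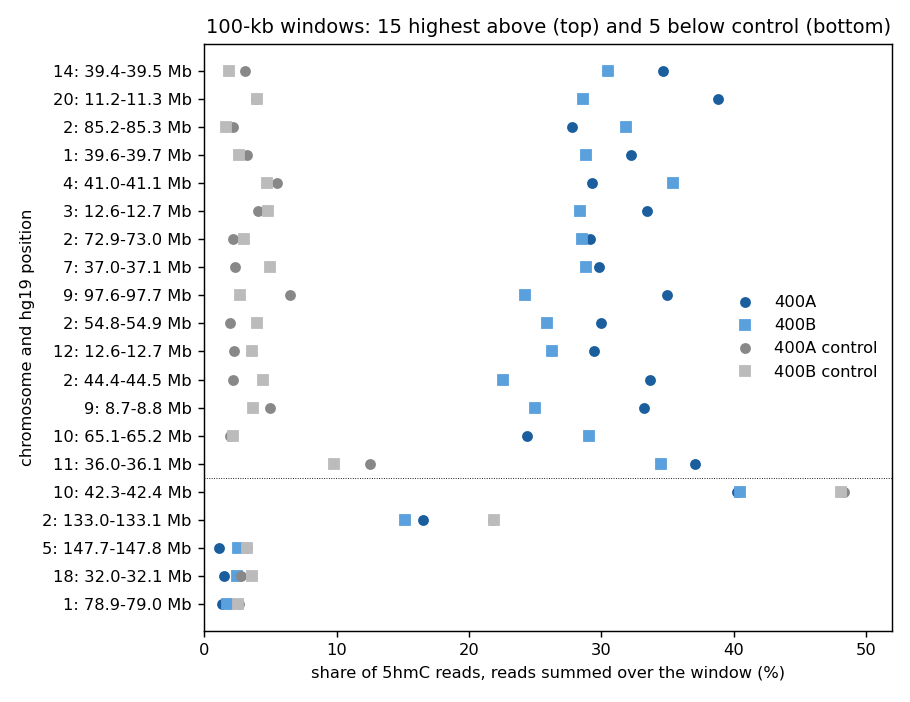
Share of reads counted as 5hmC, reads summed over the window (horizontal axis, %), in 400A, 400B and their controls for the 20 named 100-kb windows (vertical axis, chromosome and hg19 position in Mb). Above the dotted line both brain libraries lie far to the right of both controls; below it the controls lie to the right, and the chromosome 10 window has control levels of 48.4% and 48.1%.

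At single cytosines, brain gave many calls in the direction of 5hmC and few in the other. Fisher's exact test called 188061 of 2384466 cytosines higher in 400A than in its control and 5090 lower, and 136917 of 2446731 higher in 400B and 6424 lower. The median level of the higher calls was 34.1% in 400A and 31.4% in 400B, with a median of 0 in the controls. The calls were made on these same reads, which favours high library and low control levels. Among the 2155549 cytosines tested in both pairs, 175692 were called higher in the A pair and 125786 in the B pair. They shared 50179, against 10252 for independent lists of these sizes. The Brain pair gave 8159 higher and 12 lower calls, Spleen 265 and 51, Kidney 38 and 1, and Liver 3 and 0. In DKO, Fisher's exact test with Benjamini-Hochberg adjustment called 0 cytosines in either direction, with 7486 higher and 3402 lower at an unadjusted p below 0.05. As yardsticks, 400A against 400B gave 18633 higher and 6808 lower calls, and their controls against each other 1178 and 1549. Both yardsticks exceed the calls of Spleen, Kidney and Liver. The 18633 higher calls between 400A and 400B also exceed the 8159 of the Brain pair. Pairs of different depth are not comparable by their number of calls: on simulated reads, 64.6% of 40-point differences were called at the depths of the 400A pair and 24.9% at those of the Brain pair. At an adjusted p below 0.01 the higher calls fell to 99068 in the 400A pair, 66515 in the 400B pair and 2390 in the Brain pair.

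The cytosines called in both 400 pairs were also the cytosines with more signal in other tissues. At these cytosines the Brain library exceeded its control by 22.9 points, against 5.16 points at the other tested cytosines. The corresponding differences were 6.45 against 1.24 points in Spleen, 5.89 against 1.76 in Liver and 4.91 against 1.03 in Kidney, each above control on 22 of 22 autosomes. In DKO they were 0.112 points, above control on 17 of 22 autosomes, against 0.0749 points.

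**Figure D3:**
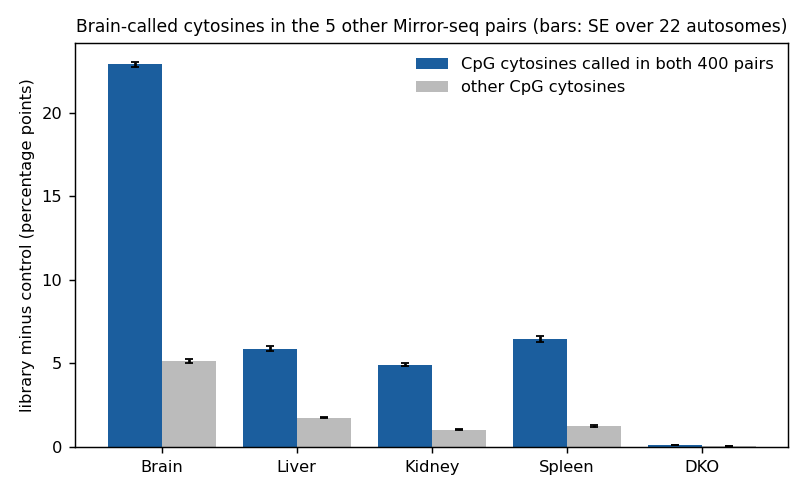
Library minus negative control (vertical axis, percentage points) for the Brain, Liver, Kidney, Spleen and DKO pairs, at cytosines called higher in both 400 pairs (blue) and at the other tested cytosines (grey), with the standard error over the 22 autosomes. The blue bars are 22.9 points in Brain, 4.91 to 6.45 points in the other tissues and 0.112 points in DKO.

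The replicates and the lower inputs show how well brain levels repeat. Across 3003578 cytosines 400A and 400B correlated with r = 0.625 (Spearman 0.460), and their difference had an SD 1.51 times that of binomial sampling. Their controls correlated with r = 0.562 (Spearman 0.0893) across 2778330 cytosines, so Pearson's r alone does not show that 5hmC repeats. With at least 50 and at least 100 reads in both 400A and 400B, minimums chosen after seeing the data, 401551 and 29283 cytosines remained. There r was 0.762 and 0.883 and Spearman's coefficient 0.486 and 0.523, while the SD of the difference was 1.68 and 1.89 times that of binomial sampling. The controls were not compared at these minimums. Control-subtracted levels of 13299 windows correlated with r = 0.888 between 400A and 400B and 0.880 between 400A and Brain. The 200 ng library averaged 9.97% and the 100 ng library 9.28%, where the 400 libraries averaged 8.57% ± 0.58 (SD, n = 2) over the same 1176795 cytosines. The excess of 1.40 points at 200 ng was larger than the SD between the replicates, and that of 0.717 points at 100 ng slightly larger. With both cytosines of a CpG summed the excess at 100 ng, 0.631 points, was smaller than the SD of 0.644 points. Across cytosines 400A correlated at r = 0.553 with the 200 ng library and 0.588 with the 100 ng library, against 0.607 with 400B. Mean depths were 25.4 reads at 200 ng, 33.7 at 100 ng and 40.7 in 400A. Each input was 1 library without a control, from another set than the 400 libraries.

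Among tissues, brain stood apart over a large part of the genome. Over 9322 windows measured in all 4 tissues, the control-subtracted level was highest in Brain in 80.9%, in Liver in 11.2%, in Kidney in 4.40% and in Spleen in 3.55%. Brain exceeded the mean of the other 3 tissues by more than 6.93 points, the 99th percentile of the difference between 400A and 400B, in 1510 windows. The 8 largest were chromosome 8, 4400001 to 4500000 (21.6 points over control in Brain against 0.467 in Liver, 1.28 in Kidney and 0.967 in Spleen), chromosome 10, 129800001 to 129900000 (21.1 points in Brain), chromosome 15, 72000001 to 72100000 (21.2), chromosome 17, 9100001 to 9200000 (22.5), chromosome 2, 29200001 to 29300000 (19.8), chromosome 4, 99400001 to 99500000 (19.1), chromosome 18, 44200001 to 44300000 (17.8) and chromosome 7, 98600001 to 98700000 (22.3). All 8 were also above control in the 400A pair, by a median of 17.4 points, and in the 400B pair, by a median of 14.3 points. Liver exceeded the others in 2 windows, chromosome 15 at 72600001 to 72700000 (6.10 points over control, with Brain at -3.21 points) and chromosome 18 at 61200001 to 61300000 (8.96 points, with Brain at 4.08 points), and Kidney and Spleen in 0. As means over all cytosines covered in each pair, the chromosome 18 window was higher in Brain (7.61 points) than in Liver (6.67 points), and the chromosome 15 window was at 4.82 points in Liver and -1.63 points in Brain. The 400A and 400B pairs gave 6.38 and 5.30 points in the chromosome 18 window. In the chromosome 15 window they gave 2.73 and 2.15 points, so the negative Brain value was not repeated. In the lower direction 0 windows of Brain, 21 of Liver, 50 of Kidney and 14 of Spleen passed the limit. Brain is part of the mean that Liver, Kidney and Spleen were set against, so its excess largely fixes their counts in both directions. With a limit of 8.70 points, taken after seeing the data from 400 libraries that were both control-subtracted and thinned to 10 reads, 785 Brain windows and 0 Liver windows passed in the higher direction. Control-subtracted window levels correlated between tissues with r from 0.399 for Liver and Kidney to 0.586 for Brain and Spleen. The 0.880 between 400A and Brain came from 13299 other windows. Mean window signals were 1.52 points in Liver, 0.855 in Kidney and 1.05 in Spleen, against 4.87 in Brain. Noise weighs more on weaker signals, so these correlations do not measure how far the tissues differ.

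The difference from control was smaller at CpG-dense sites in every tissue, and too small in the cell line to show such a dependence. In 400A the difference from control was 10.6 points at cytosines with 1 to 3 covered CpGs within 100 bp, 7.54 points with 8 to 11, and 2.09 points with 20 or more, and in 400B it was 9.60, 6.54 and 1.34 points. In Brain it went from 9.31 to 0.886 points between the sparsest and the densest class, and in Liver from 2.58 to 0.712 points. In Spleen and Kidney it went from 2.18 and 2.03 points to values just below control, -0.0352 and -0.0741 points; with at least 20 reads per cytosine the Spleen value was 0.0224 points. In DKO it stayed between 0.0476 and 0.0812 points in all 6 classes. Controls varied less with density than brain libraries: the 400A control lay between 2.68% and 3.56% over the 6 classes, and 400A between 4.77% and 13.9%.

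**Figure D4:**
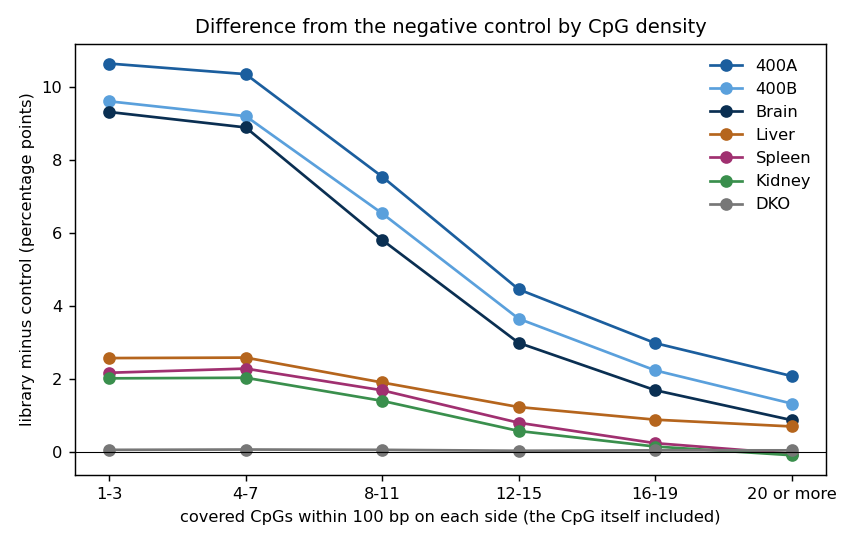
Library minus negative control (vertical axis, percentage points) by the number of covered CpGs within 100 bp on each side (horizontal axis, the CpG itself included) for the 7 Mirror-seq pairs. The 3 brain lines fall from 9.31 to 10.6 points at low density to 0.886 to 2.09 points at high density, and the DKO line lies near 0 throughout.

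Liver tumor and adjacent normal liver differed little in mean level. The mean level was 3.56% in the tumor library and 3.77% in the adjacent normal library, a difference of -0.205 points that had the same sign on 22 of 22 autosomes. Whether the size of this difference exceeded the SD of the 7 Mirror-seq controls depended on the cytosines and on how reads were averaged. The SD of the controls was 0.234 points, each over the cytosines of its own pair. Over the 393189 cytosines covered in every Mirror-seq library the difference was -0.269 points and the SD 0.163 points. The size of the difference was also above the SD with at least 20 reads (-0.189 points, SD 0.154) and with pooled reads (-0.230 points, SD 0.189). This SD describes single libraries. A difference between 2 independent libraries varies more than single libraries do, so a size above the SD does not show an excess over the spread. Fisher's exact test called 4 cytosines higher and 3 lower in the tumor out of 1942883, with 12128 and 17125 at an unadjusted p below 0.05. Of 17289 windows, 0 passed the limit of 6.93 points in either direction, so no region is named. That limit came from brain libraries with higher levels, and the tumor minus normal difference had an SD of 0.919 points over windows. With adjacent normal liver at 3.77% on average few windows could fall past it, so the 0 does not show that windows were unchanged. The tumor library was the lower in 61.6% of windows. With cytosines of at least 5 reads 2 windows rose and 1 fell, and with the 95th percentile as limit 8 rose and 15 fell. Neither library had a negative control, and each stood for 1 sample.

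TAB-RRBS levels followed the Mirror-seq brain levels in the library labelled control and hardly in the library labelled TAB-RRBS. The mean level was 4.95% in the library labelled TAB-RRBS and 13.9% in the library labelled control, so the labelled difference was -8.98 points, with the same sign on 22 of 22 autosomes. Across 1887230 cytosines, the mean of 400A and 400B correlated with r = 0.0997 (Spearman 0.199) with the library labelled TAB-RRBS and r = 0.508 (Spearman 0.581) with the library labelled control. From cytosines with a 400 difference below 0 to those with 50 points or more, the library labelled control went from 4.79% to 42.1%, and the library labelled TAB-RRBS from 2.51% to 5.55%. Fisher's exact test called 164898 of 2660761 cytosines lower and 734 higher in the library labelled TAB-RRBS. Of the 30419 cytosines called in both 400 pairs and tested here, 12255 (40.3%) were also called higher in the library labelled control, against 1944 for independent lists, and 0 in the other direction, against 9.38. At the cytosines called in both 400 pairs the libraries stood at 5.07% as labelled TAB-RRBS and 33.2% as labelled control. The titles and the file names label this pair in opposite ways, and the values go with the file names. They argue against the titles, since the library labelled TAB-RRBS read only 5.55% where the 400 difference was 50 points or more. Each TAB-RRBS group is 1 library.

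**Figure D5:**
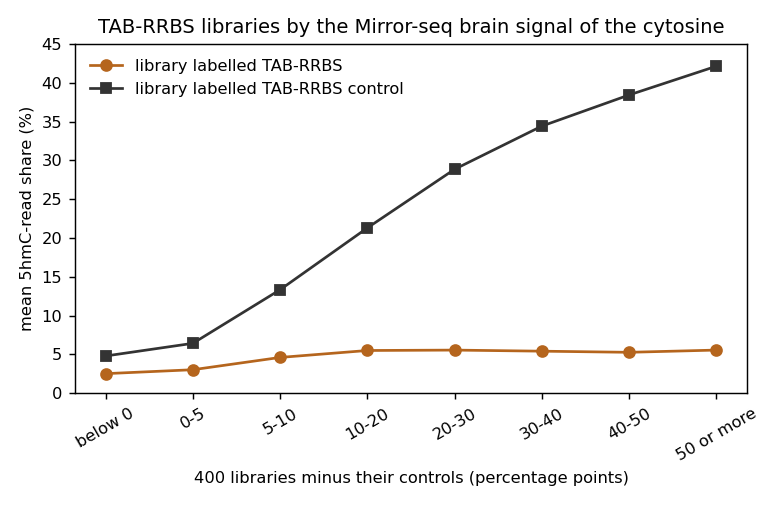
Mean percentage of reads counted as 5hmC (vertical axis) in the 2 TAB-RRBS libraries, by the mean difference of 400A and 400B from their controls at the same cytosine (horizontal axis, percentage points). The library labelled control rises from 4.79% to 42.1%, and the library labelled TAB-RRBS lies between 2.51% and 5.55%.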

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

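The tests of explanations in this part were chosen only after the results were seen, although the exchange of the TAB-RRBS labels was already part of the plan. The library labelled TAB-RRBS lay below its labelled control by 8.98 points (a difference of -8.98), while all 7 Mirror-seq pairs, 3 of them from brain, lay above theirs. The opposite sign was not tested, since each TAB-RRBS group is 1 library. The sign was the same in all 6 density classes, with differences of -15.6, -13.2, -9.05, -4.48, -2.29 and -1.17 points from the sparsest to the densest, and both at cytosines called in the 400 pairs (-28.1 points) and at other cytosines (-7.38 points). An even background in the library labelled control is argued against, because its excess was 34.3 points larger at cytosines with a 400 difference of 50 points or more than at those below 0. Exchanged labels of this pair may account for the pattern: the library labelled control is the one that follows the Mirror-seq brain signal (r = 0.508 against 0.0997), and the names of the deposited files also give the exchanged assignment. No biological explanation was tested.

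At cytosines with 20 or more covered CpGs within 100 bp, Kidney and Spleen lay below their controls by small amounts (-0.0741 and -0.0352 points) where both 400 pairs lay above theirs. These differences were not tested against each other, and with at least 20 reads per cytosine the Spleen difference was 0.0224 points and the Kidney difference -0.0770 points. With at least 5 reads Kidney and Spleen stood at -0.0964 and -0.0933 points. In the densest class within 500 bp they stood at -0.121 and -0.0683 points.

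The mitochondrial genome was outside the comparisons. There the share of reads counted as 5hmC exceeded that of the control, with separate 95% Wilson intervals, by 1.73 points in 400B (8.86% against 7.13%), by 1.15 points in Spleen (5.31% against 4.17%) and by 1.01 points in the library labelled TAB-RRBS (2.64% against 1.63%). In 400A the shares were 8.53% and 8.2%, and in Brain the library was the lower, 4.13% against 4.77%, so the brain libraries had no common direction. The intervals cover counting error only.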

How the results depend on the processing

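The coverage minimums of 50 and 100 reads, the limit from control-subtracted and thinned 400 libraries, the averaged brain pairs, the single-library leave-outs and the coverage settings of the limma count were added after seeing the data; all others were planned. Of 475 values under alternatives, 328 stayed within their spread, within a fixed ratio for counts, or on their side of the threshold. Another 122 moved further, 25 lost their call and 0 changed direction. Counts of calls and windows cannot change direction. Agreement of 400A and 400B and mean levels without control subtraction had no bound and were always taken as moved. Outside these values, the Spleen difference in the densest class went from -0.0352 to 0.0224 points at 20 reads. Exchanging the TAB-RRBS labels turned the control-subtracted correlation with the 400 libraries from -0.558 to 0.558 by construction. As means over cytosines, 2 of the 5 lower windows lay above control in the A pair and 3 in the B pair. In the exact sign-flip test the 7 pairs kept p at 0.0156 under the 6 processing alternatives and at 0.0313 with any pair left out (means of 2.71 to 3.85 points), the smallest values 7 and 6 pairs allow. With 400A and 400B averaged the mean was 2.79 points with p at 0.0313, and with the 3 brain pairs averaged 2.15 points with p at 0.0625, where 5 pairs cannot reach 0.05. The limma count of 14750 higher windows was 14709 with the replicate letter as a replicate block, and that of 5 lower windows was 4. The letters need not pair the libraries, since their deviations from A to B correlated at -0.0125 between the 400 libraries and their controls, and only 2 pairs exist. Leaving out 1 library gave 12986 to 14533 windows, with the lone library assumed to vary like the others. Leaving out a whole replicate leaves no residual degrees of freedom, so no count was made; the median window difference was then 4.95 to 5.78 points and the mean difference of the 400 pairs 6.01 to 6.95 points. Other window minimums, added counts and coverage minimums gave 9974 to 20397 of 10468 to 23590 windows. Of the named windows, the 15 higher in the 400 libraries and the 8 of Brain stayed past their limit wherever they could be measured, while each of the 5 lower windows and both Liver windows lost theirs under at least 2 alternatives.

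Mean differences were smaller in size at a higher coverage minimum in all comparisons but DKO; such a minimum also changes which cytosines are averaged. For the 400 mean, Brain, Liver, Kidney, Spleen and labelled TAB-RRBS they were 7.21, 6.29, 1.94, 1.22, 1.42 and -9.42 points at 5 reads and 5.53, 4.68, 1.85, 1.12, 1.33 and -8.14 at 20 reads, where DKO rose from 0.0701 at 10 reads to 0.080 and tumor minus normal -0.189. Pooled reads gave 5.71, 5.39, 1.93, 1.27, 1.23 and -8.35, with 0.0595 in DKO and -0.230 for the tumor. Cytosines covered in every Mirror-seq library gave 5.37, 5.25, 1.70, 0.978, 1.33 and -7.21, with 0.0844 in DKO and -0.269 for the tumor. Both cytosines of a CpG summed gave 7.25, 6.14, 1.93, 1.21, 1.42 and -9.59. Without the top percentile of coverage Brain, Spleen and labelled TAB-RRBS gave 5.71, 1.40 and -9.03. Without control subtraction Brain, Liver, Kidney, Spleen and DKO stood at 8.81, 4.69, 4.35, 4.92 and 3.02%. For these shifts the cause was not tested.

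Depth limits the calls, as simulated reads showed. Thinned to 10 reads, calls were 874 higher and 10 lower in 400A and 0 in 400B, Brain, Liver, Kidney, Spleen, the tumor in both directions, and the lower calls of labelled TAB-RRBS; with 10 reads on each side few differences can pass, so these counts say nothing of stability. At 0.01 higher calls were 99068, 66515, 2390, 1, 17 and 114 in 400A, 400B, Brain, Liver, Kidney and Spleen, the tumor had 1 higher and 0 lower, and labelled TAB-RRBS 77093 lower. Summing both cytosines gave 215434 in 400B, 25878 in Brain, 17 in Liver, 146 in Kidney, 1389 in Spleen, and 8 higher and 8 lower in the tumor. Kidney had 23 calls at 5 reads and 62 at 20; the tumor had 7 higher and 9 lower at 20. DKO had 0 calls under every alternative. Agreement of 400A and 400B was r = 0.603 at 5 reads, 0.664 at 20, 0.762 at 50, 0.883 at 100 and 0.680 with both cytosines summed. The sparse minus dense difference, 8.54 in 400A and 8.26 in 400B, was 9.19 and 8.72 points with density within 500 bp and 8.31 and 8.05 at 5 reads.

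Brain windows above the other tissues numbered 224 at 20 reads, where 1157 windows were measured, 3233 with the 95th percentile and 785 with the limit from control-subtracted and thinned libraries, which changes 2 choices at once. Liver windows were then 0, 19 and 0, and 1 both at 5 reads and without control subtraction. Spleen had 2 at 5 reads and 1 with the 95th percentile, where Kidney had 5. Tumor windows were 2 higher and 1 lower at 5 reads, and 8 higher and 15 lower with the 95th percentile. The labelled TAB-RRBS correlation with the 400 mean was 0.0786 at 5 reads, 0.134 at 20 and 0.508 with the 2 TAB libraries exchanged.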

Other observations

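All tests in this part were chosen only after the results were seen. Neighbouring CpGs had related levels in brain. On the plus strand, 400A at a CpG and 400B at another correlated with r = 0.353 for CpGs 2 to 10 bp apart, 0.301 at 51 to 100 bp, 0.187 above 250 and up to 1000 bp and 0.0486 above 1000 and up to 10000 bp. In the controls the same values were 0.0632, 0.0203, 0.0136 and 0.00495. At the same CpG the correlation was 0.626 in the 400 libraries and 0.575 in the controls. Over the cytosines of both strands the controls correlated at 0.562 by Pearson's and only 0.0893 by Spearman's coefficient. CpG pairs are not independent, and no p was computed.

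Chromosomes 19 and 22 had the largest differences from control in all 3 brain pairs and in Liver: 8.25 and 8.24 points in 400A, 7.22 and 7.11 in 400B, 6.68 and 6.83 in Brain, and 2.38 and 2.35 in Liver. Chromosome 19 was also the highest in Kidney (1.5 points) and in Spleen (2.03 points). Chromosome 5 was the lowest in 400A (5.94 points), 400B (5.15), Brain (4.86) and Liver (1.53). In DKO the differences ran from 0.0251 points on chromosome 20 to 0.165 points on chromosome 21.

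The tumor library was below adjacent normal liver on every autosome, by a small amount. Loss of 5hmC where normal liver has most of it was the biological candidate, and a background offset between the 2 libraries the technical one. From the bottom to the top 20% of windows by Liver minus control the fall changed by -0.0386 points (SE 0.026), from -0.177 to -0.216. The 2 cannot be told apart by this, since the adjacent normal library itself rose only from 3.18% to 3.41% while Liver minus control went from -0.180 to 4.23 points. At cytosines called in both 400 pairs the fall was larger by -0.163 points, and 4 of 10 comparisons among 5 controls gave a larger size, up to 0.526 points. All 4 involve the Brain control; of the 6 comparisons without it 0 were larger, the nearest at -0.149 points. That background alone could give the extra fall therefore rests on 1 library, and a small loss of 5hmC stays open beside it. That the adjacent normal library carries 5hmC like the Liver library is argued against: from the bottom to the top 20% of windows by brain signal it rose by 0.522 points and the tumor library by 0.492, against 2.55 points in Liver. The Brain control rose by 0.555 points, and those of Kidney, Spleen, Liver and DKO by 0.137 to 0.443. Different donors, sample handling or library sets stay open and were not tested.

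The 2 strands of a CpG differed in a way that repeated between libraries. Over 286060 CpGs with at least 10 reads on both strands, the strand difference in 400A correlated with that in 400B at r = 0.131, and the correlation of levels was 9.72% lower between opposite strands than within a strand. The controls lost 9.32% against each other. Their strand differences correlated at r = 0.0966. That strand-specific 5hmC is the only source is argued against, since these controls averaged 3.18%, near the 3.02% of the DKO library. Whether 5hmC adds to a source in the method cannot be told. The loss of 400A against the library labelled TAB-RRBS control was 39.4% of its loss against Brain. For 400B the losses were 2.28% and 9.30% in these comparisons. They count against 5hmC only if that library reads 5hmC, which its file name gives and its title does not. Against the 400B control 400A lost 7.11%, near the 7.81% against Brain. The labels do not say what the controls lack, so a small 5hmC signal in them stays possible. Sequence context on each strand was not tested.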
